A study of Oryza coarctata with 5 samples.

How the data were processed

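RNA-sequencing of mature *Oryza coarctata* plants was analysed from 5 expression tables, 1 for each treatment: water control, 450 mM NaCl, 700 mM NaCl, submergence in water and submergence in 450 mM NaCl. Per the labels, plants came from natural conditions, total RNA was isolated with TRI reagent and libraries were made with an Illumina mRNA kit, which selects polyadenylated RNA. The labels name mature plants as the source, and the series text speaks of different tissue samples without naming them. Duration of treatment, plants per library and sequencing batch are not given in the sources used here.

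The deposited values are RPKM (reads per kilobase of transcript, scaled to the read total of the library), which the authors calculated for each assembled transcript. Per the series text, reads were filtered by the authors with NGS QC Toolkit and mapped to assembled *Porteresia* transcripts. The mapping program, program versions and details of the assembly are not given in the sources used here, nor is the handling of reads that map to several transcripts. In a polyploid species, near-identical gene copies can share reads, so single transcripts of such copies are less certain than their read counts imply. The authors' own differential expression analysis used DESeq, per the series text, and its output was not used here.

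RPKM values of 1 transcript were whole multiples of a unit set by its length and the library's read total. These steps were solved for the read total of each library, the length of each transcript and whole reads. The minimum length was 200 nt, and each value had to lie within a small tolerance of a whole read. A solution was found for 152263 transcripts, 100% of those above 0, and 99.98% of values above 0 came within 0.01 of a whole number. The tolerance largely sets this closeness, so it is no check of the recovery. The recovered median length was 470 nt. Recovered reads summed to 99.1% of the solved read total in each library. Read totals were 56638106 reads for the water control, 59818908 for 450 mM NaCl, 58431819 for 700 mM NaCl, 78997373 for submergence in water and 74867531 for submergence in 450 mM NaCl. On simulated data 97.8% of transcripts had all their read numbers recovered exactly. For the rest the solution was a smallest one, of which the true read numbers were multiples, and the same can hold for some transcripts here. Reads and lengths served only for counting intervals, simulated libraries, thinning and the definition of transcript sets. RPKM was used as deposited for every comparison.

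With 1 library per treatment no test between treatments was run. An additive model of salt dose and submergence, which would leave 1 residual degree of freedom, was not fitted. In 7 comparisons, a transcript was called higher or lower at a log2 ratio of RPKM + 0.5 of at least 1 or at most −1, among transcripts with RPKM of at least 1 in at least 1 of the libraries compared. Departure from additivity used a limit of 2 on the log2 scale, since noise of 4 libraries adds. Overlaps are set beside the number that independent lists of the same sizes would share. For higher calls against the shared control this used all transcripts measurable in either comparison, because a low control value makes the filter depend on the treated library. Correlations of log2 ratios were computed across transcripts for 8 pairs of contrasts, 6 of which share no library. Simulated libraries without a difference were drawn 20 times from Poisson distributions with the recovered depths. Intervals are exact 95% intervals for reads (Poisson) and for ratios of reads (Clopper-Pearson). All of these cover counting error only. On simulated data for 450 mM NaCl against control, the calling rule found 28.8% of 66 transcripts given a 2-fold difference, 95.8% of 72 given 4-fold and 98.4% of 62 given 8-fold, and it called 0.125% of 69462 transcripts given none.

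The comparisons, limits, alternatives and the rule for naming transcripts were fixed before the data were examined. The rule took the transcript with the largest smaller-of-2 rise and the one with the largest smaller-of-2 fall over 450 mM and 700 mM NaCl against control, and likewise over the contrasts of submergence without and with salt, among transcripts reaching RPKM 10 in at least 1 of the libraries used. Gene lists for ion transport, osmoprotection, anaerobic metabolism and other functions had been fixed too, but the transcript numbers carry no gene names and the lists could not be applied.

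The alternative settings were a pseudocount of 0.1 or 1, no filter on low values or a filter at RPKM 5, median-of-ratios scaling, equal sums of RPKM, a limit to differences beyond counting error, detection at RPKM 1, and the share of the 10 most abundant transcripts. Another 3 were added after seeing the data: leaving out the transcripts with at most 1 read at 700 mM NaCl and at least 100 in the other 4 libraries together, leaving out the transcripts seen only in the control, and thinning reads to the smallest library total. No paired analysis was possible because each treatment has 1 library and no replicate numbers. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.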

Results

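The transcriptome of *Porteresia* (*Oryza coarctata*), a wild relative of rice that grows in saline, regularly flooded coastal soils, was measured in 5 RNA-sequencing libraries from mature plants collected in nature. Each of 5 treatments was represented by 1 library: a water control, 450 mM NaCl, 700 mM NaCl, submergence in water, and submergence in 450 mM NaCl. There were no replicates, so the spread between plants of 1 treatment is unknown, no test between treatments was run and no p-value is given. A transcript is called higher or lower in a comparison by size alone, at 2-fold or more after adding 0.5 to both RPKM values (reads per kilobase of transcript, scaled to the read total of the library), with RPKM of at least 1 in at least 1 of the libraries compared. The fold on this scale understates differences of low transcripts. Transcripts carried assembly numbers without gene names, so the values below describe groups of transcripts and not named genes or pathways. All counts are of assembled transcripts, several of which can belong to 1 gene.

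Expression values were listed for 152367 transcripts, of which 104 were at 0 in every library. The steps between low RPKM values gave the read total behind each library: 56638106 reads for the water control, 59818908 for 450 mM NaCl, 58431819 for 700 mM NaCl, 78997373 for submergence in water and 74867531 for submergence in 450 mM NaCl. The numbers of transcripts with RPKM above 0 were, in the same order, 146599, 145610, 140749, 146477 and 146441. Those with RPKM of at least 1 numbered 65480, 61939, 64328, 66377 and 63095. The 100 most abundant transcripts held 9.44% of the summed RPKM in the water control, 10.3% at 450 mM, 10.97% at 700 mM, 9.42% in submergence in water and 8.95% in submergence in 450 mM NaCl. Across the 86834 transcripts at RPKM of at least 1 in any library, log2 values of the water control correlated most closely with those at 450 mM NaCl (Pearson r 0.95) and least with those of plants submerged in water (r 0.86). The lowest correlation of any pair was that of 700 mM NaCl with submergence in water (r 0.73). These correlations run across transcripts, which are not independent replicates.

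A pair of transcript sets is set beside the counts that follow because each was bound to 1 library. In the 700 mM NaCl library, 1919 transcripts had at most 1 read each although the other 4 libraries together held at least 100 reads for each of them. This set accounted for 132933 reads (0.235%) in the water control, 375159 (0.627%) at 450 mM NaCl, 555350 (0.703%) in submergence in water and 192831 (0.258%) in submergence in 450 mM NaCl, against 78 reads at 700 mM. In the other set, 273 transcripts had RPKM of at least 1 in the water control and at most 1 read in each other library. Their median RPKM in the control was 1.65. A transcript with at least 100 reads in the control can belong to both sets.

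**Figure D1:**
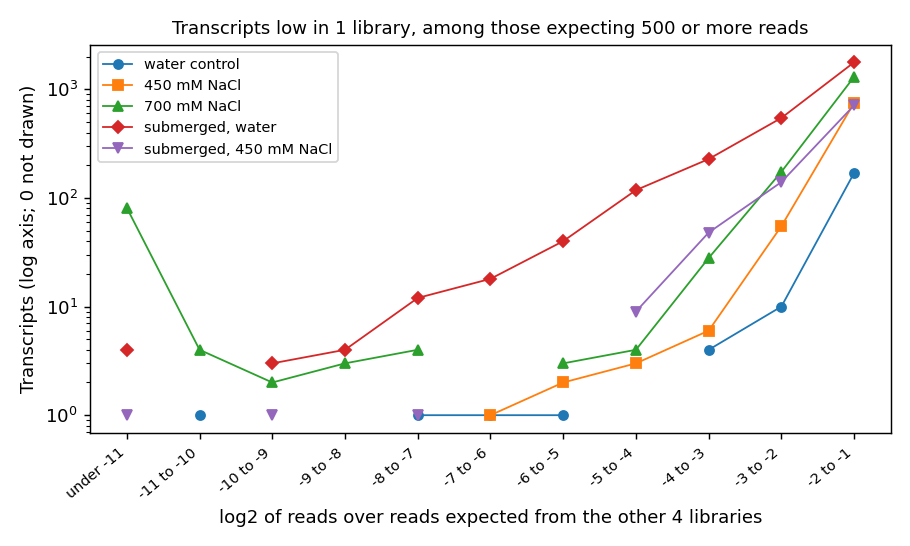
Number of transcripts (log axis) by the log2 of their reads in 1 library over the reads expected from the other 4, for transcripts expecting at least 500 reads and lying at least 2-fold low. Lines are the 5 libraries, and empty bins are not drawn. In the 700 mM NaCl library 81 transcripts lay below −11 and 16 from −11 to −5, whereas submergence in water had 4 and 77.

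The comparison of 450 mM NaCl with the water control asked how the plants' transcripts differed at the lower salt dose. Among 71076 transcripts, 2073 (2.92%) were higher in salt and 2404 (3.38%) were lower. At 4-fold or more, 229 were higher and 350 lower. Of the 229, 181 lay in the set missing from the 700 mM library, and 164 of the 350 were seen only in the control. Of all 2073 higher transcripts, 1011 belonged to the set missing from the 700 mM library, and without that set 1062 were higher. Of all 2404 lower transcripts, 273 were the ones seen only in the control. The balance of directions moved with the scaling and with that set. With RPKM as deposited 46.3% of the calls were higher, against 61.1% after median-of-ratios scaling, whose log2 factor for this library was −0.16 relative to the control. Without the set missing from the 700 mM library the share was 31.1%.

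At 700 mM NaCl, 3324 of 73464 transcripts (4.52%) were higher than in the water control and 3588 (4.88%) were lower. At 4-fold or more, 124 were higher and 694 lower, and 331 of these 694 lay in the set missing from this library. Of the same 694, 164 were transcripts seen only in the control, which can include members of that set. Higher calls made up 48.1% of the calls with RPKM as deposited and 58.8% after median-of-ratios scaling (log2 factor −0.10).

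The doses were also compared directly. Between 700 mM and 450 mM NaCl, 2831 of 70838 transcripts were higher at the higher dose and 2600 were lower, with 99 and 1110 at 4-fold or more. The set missing from the 700 mM library supplied 1348 of the lower transcripts (51.8%) and 976 of those at 4-fold. Without it, 1252 were lower, and the share of calls that were higher went from 52.1% to 69.3%. Of the 2600 lower transcripts, 1777 stood at RPKM 0 at 700 mM, more than the 1348 in the set. Some of the 1252 were therefore also without reads in that library. Against the control, 259 transcripts were called higher at both doses. Independent lists of 2073 and 3324 among the 76653 transcripts measurable in either comparison would share 89.9. Of the 2073, 1011 lay in the set missing from the 700 mM library and could not be higher there, which inflates the 89.9. Another 1253 transcripts were lower at both doses, where independent lists of 2404 and 3588 among the 67887 measurable in both comparisons would share 127. Both comparisons used the same control library. Libraries simulated with no difference, which vary by counting error only, shared on average 4.75 higher and 3.25 lower calls from that control. Other differences of the control library were not simulated. The part of these overlaps that comes from the control itself could therefore not be separated. The 1253 included 273 transcripts seen only in the control.

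Transcripts higher at 450 mM NaCl had a median log2 ratio to control of 1.36 at 450 mM and −0.44 at 700 mM. Without the set missing from the 700 mM library, which was chosen by its absence there, these medians were 1.25 and 0.40. Transcripts lower at 450 mM had medians of −1.30 and −1.04, or −1.29 and −1.02 without that set. Those called higher at 700 mM had a median of 1.24 at that dose and 0.39 at 450 mM. For those called lower at 700 mM the medians were −1.34 and −0.75, or −1.26 and −0.83 without that set. All these ratios use the same control library, which pulls the medians toward a like sign by an amount not measured here.

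The transcripts with the most extreme values over both salt doses were picked by a rule fixed in advance. Pc_TC079114 (380 nt) stood at 1.02 RPKM in the water control (22 reads) and 13.5 at 450 mM (308 reads), and it had 333 reads at 700 mM. It was thus 13.3-fold higher (95% interval 8.60 to 21.5) and 14.7-fold higher (9.53 to 23.7), and in submergence in 450 mM NaCl it stood at 8.26 RPKM. Pc_TC140225 (1018 nt) stood at 60.5 RPKM in the control from 3491 reads and at 0.31 at 450 mM from 19 reads, which is 194-fold lower (124 to 323). It had 0 reads at 700 mM, at least 1200.5-fold lower than the control with a floor of 3 reads, the 1-sided 95% limit of a count of 0 (the 2-sided exact 95% interval of the ratio starts at 976-fold). This transcript was also near 0 in both submerged libraries, at 0.17 and 0.066 RPKM, and belongs to the set missing from the 700 mM library. The intervals cover counting error only, not differences between plants.

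Submergence in water, the condition of a plant covered by fresh water, gave the largest counts of the 4 treatments set against the control. Of 77196 transcripts, 9372 (12.1%) were higher and 9153 (11.9%) lower than in the water control, with 968 and 1948 at 4-fold or more. The set missing from the 700 mM library held 971 of the higher transcripts, and 273 of the lower ones were those seen only in the control. Transcripts called higher under water had a median log2 ratio to control of 1.34 there, 0.62 in submergence in 450 mM NaCl, −0.16 at 450 mM NaCl without submergence and −0.37 at 700 mM. Transcripts called lower under water had medians of −1.47, −0.91, 0.06 and 0.29 in the same order. These ratios share the control library as well. After median-of-ratios scaling the medians at 450 mM NaCl were −0.06 for the higher and 0.20 for the lower transcripts.

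Plants submerged in 450 mM NaCl differed from the water control in fewer transcripts than plants submerged in water. Of 72288 transcripts, 2635 (3.65%) were higher and 4999 (6.92%) lower, with 111 and 732 at 4-fold or more. Higher calls made up 34.5% of the calls with RPKM as deposited and 37.1% after median-of-ratios scaling. Under water with and without salt, 1563 transcripts were higher than in the control, where independent lists of 9372 and 2635 among the 79460 measurable in either comparison would share 311. Another 4024 were lower in both, where independent lists of 9153 and 4999 among the 70024 measurable in both would share 653. Simulated libraries with no difference shared 2.80 higher and 1.95 lower calls from the control. Of the 4024 lower transcripts, 273 were seen only in the control. With 1 control library, the part of this overlap that comes from the control itself could not be separated.

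**Figure D2:**
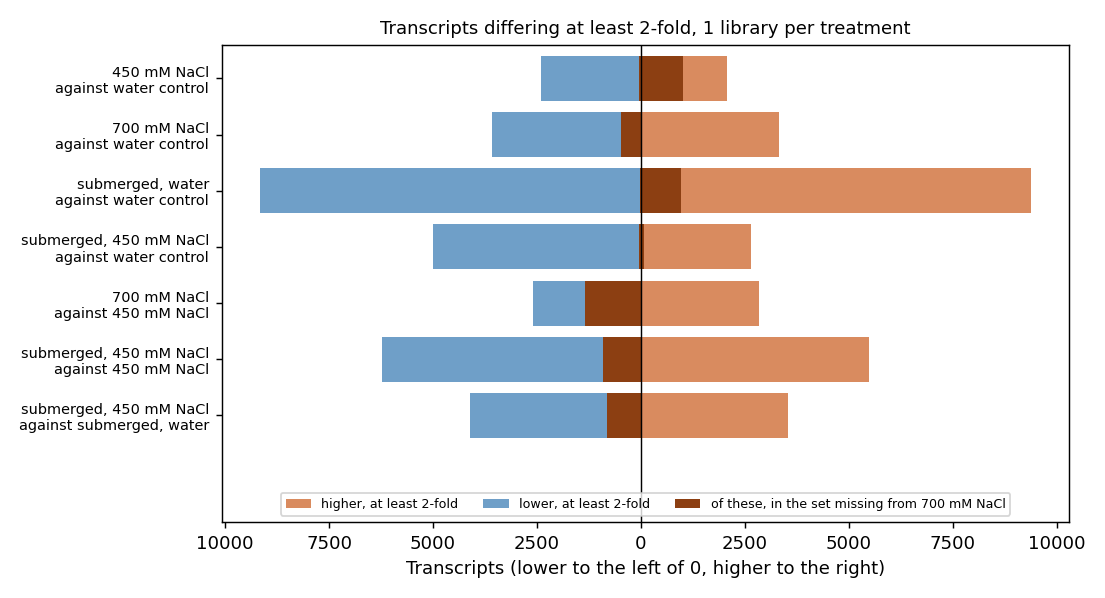
Number of transcripts at least 2-fold higher (to the right of 0) or lower (to the left) in each of 7 comparisons of single libraries, on a linear axis. The dark part of each bar is the set of 1919 transcripts missing from the 700 mM NaCl library, which supplied 1348 of the 2600 lower transcripts between 700 mM and 450 mM NaCl. The bars of submergence in water reach 9372 and 9153.

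Whether submergence acted alike without and with salt was examined in a pair of contrasts that share no library. Submergence in 450 mM NaCl against 450 mM NaCl gave 5487 higher and 6216 lower transcripts among 71650, and 906 of the lower ones were in the set missing from the 700 mM library. The higher share of these calls was 46.9% as deposited, 35.0% after median-of-ratios scaling and 50.7% without that set. Across 82365 transcripts, the log2 ratios of submergence without salt and with salt had a Pearson r of 0.63 and a Spearman rho of 0.64. Without the set missing from the 700 mM library r was 0.72, and among the 18351 transcripts reaching RPKM 10 it was 0.81. The least-squares regression slope of the contrast in salt on that in water was 0.50. Scatter lowers such a slope, so it does not measure how strongly submergence acted in salt. The standard deviations of the log2 ratios were 0.91 in water and 0.72 in salt. In both contrasts 3347 transcripts were higher (681 for independent lists) and 3781 were lower (731 for independent lists). Opposite calls were made for 704 transcripts higher in water and lower in salt, of which 583 lay in the set missing from the 700 mM library, and for 42 in the other direction.

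**Figure D3:**
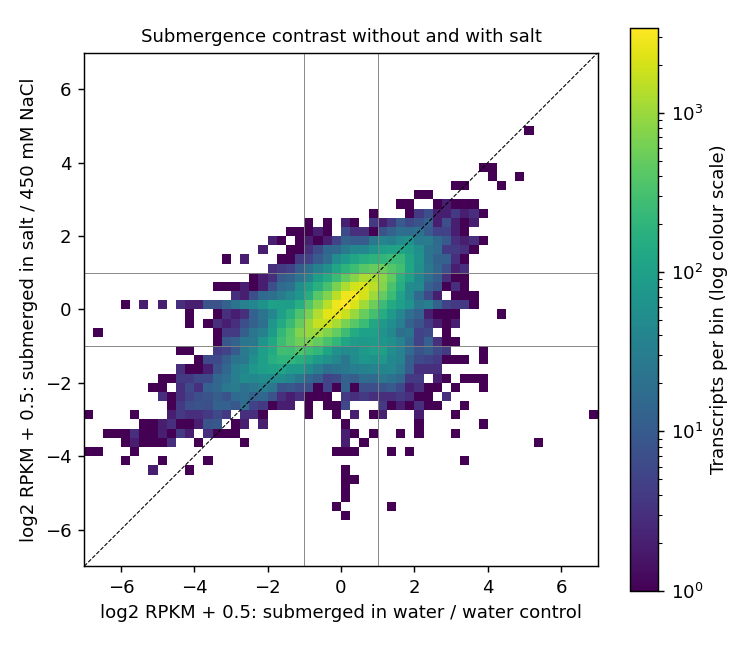
Log2 ratio of RPKM + 0.5 for submergence in salt against 450 mM NaCl (vertical axis) plotted over that for submergence in water against the water control (horizontal axis) for 82365 transcripts, with the number per bin on a log colour scale. The drawn range holds 82361 of them. Grey lines mark 2-fold and the dashed line equality. The cloud lies along a rising diagonal flatter than equality (r 0.63, least-squares slope 0.50, which scatter lowers), with a group at the lower right.

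Extreme values over both submergence contrasts were found in another pair of transcripts named by the fixed rule. Pc_TC046817 (240 nt) stood at 2.28 RPKM in the water control, 0.91 at 450 mM NaCl, 0.93 at 700 mM, 102 in submergence in water and 38.3 in submergence in salt. It was 44.9-fold higher without salt (31.5 to 66.3) and 42.3-fold higher with salt (24.6 to 79.8). Pc_TC018863 (1484 nt) stood at 22.5 RPKM in the control, 27.1 at 450 mM, 40.4 at 700 mM, 0.16 in submergence in water and 0.88 in submergence in salt. It was 139-fold lower without salt (88.6 to 231) and 30.7-fold lower with salt (25.1 to 38.0).

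The effect of 450 mM NaCl was likewise compared between plants not submerged and submerged plants. Under water, salt against no salt gave 3545 higher and 4104 lower transcripts among 72628, and 805 of the lower ones were in the set missing from the 700 mM library. The higher share of these calls was 46.3% as deposited, 51.3% after median-of-ratios scaling and 51.8% without that set. The log2 ratios of salt in plants not submerged and in submerged plants had a Pearson r of 0.22 and a Spearman rho of 0.35 across 82365 transcripts. Without a filter on low values r was 0.14, without the set missing from the 700 mM library 0.34, and among transcripts reaching RPKM 10 it was 0.42. Both contrasts called 178 transcripts higher (98.1 for independent lists) and 444 lower (134 for independent lists). Without the set missing from the 700 mM library these were 178 (52.2 for independent lists) and 421 (108 for independent lists). Another 662 were higher in salt without submergence and lower in salt under water, 542 of them in the set missing from the 700 mM library, and 46 went the other way.

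The combined treatment was finally set against the sum of its parts. The log2 ratio of submergence in salt to control departed from the sum of the separate ratios of salt and submergence by a median of 0.07 (interquartile range −0.25 to 0.39) over 82365 transcripts. At a limit of 4-fold, 593 transcripts lay above the sum and 1460 below it, where simulated libraries without a difference gave on average 0.35 and 0.30. Of the 1460, 964 were in the set missing from the 700 mM library, and without that set 568 lay above and 496 below. Of the 593, 163 were seen only in the control. Departures beyond counting error numbered 339 above and 1144 below.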

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

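All tests of explanations in this part were chosen after the result was seen. The results listed here are transcripts whose single-library contrasts pointed in opposite directions in 2 settings. The difference between the settings was not tested, since each treatment has 1 library.

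The effect of 450 mM NaCl was at least 2-fold upward in plants not submerged and at least 2-fold downward in submerged plants for 662 transcripts, and the reverse for 46. The effect of submergence was at least 2-fold upward without salt and at least 2-fold downward in 450 mM NaCl for 704 transcripts, and the reverse for 42. All these contrasts use the same 4 libraries. By construction the 662 and the 704 lie among the 1460 transcripts below additivity, and the 46 and the 42 among the 593 above it. They are therefore not separate results. Most of the 662 and the 704 came from the set missing from the 700 mM NaCl library (542 and 583). Without that set the numbers were 120 and 121, where independent lists would share 46.9 and 571. The opposite calls also varied with the settings. In the order 662, 46, 704 and 42, they were 1447, 264, 1444 and 221 with a pseudocount of 0.1, 322, 16, 318 and 13 with a pseudocount of 1, and 253, 9, 253 and 7 with a filter at RPKM 5.

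The set missing from the 700 mM NaCl library holds 1919 transcripts with a median length of 853 nt. Plant genes absent only from the plants of that library should elsewhere resemble transcripts of similar abundance, but their median log2 ratio of 450 mM NaCl to control was 1.10 (interquartile range 0.63 to 1.499), against −0.11 (−0.40 to 0.17) for matched transcripts. The tail of a graded fall at 700 mM should thin out without a separate group at its end. Among transcripts expecting at least 500 reads, the 2-fold steps from 2-fold low held 1303, 174, 28 and 4. The range from −11 to −5 on the log2 scale held 16, and 81 lay below. That lowest range gathers transcripts at 0 reads whatever the size of their fall, so a graded fall to 0 reads could end there too. The counts also leave out the part of the set expecting fewer reads. They therefore do not decide against a graded fall. A candidate explanation that stays open is another organism living on or in the plants and missing from the 700 mM library, since 89.3% of the set was higher at 450 mM NaCl than in control, as 1 source varying in amount would give. A jointly regulated group of plant genes switched off at 700 mM would give this too and was not tested, because no transcript could be named. Neither explanation covers the 50 transcripts of the set called lower at 450 mM NaCl than in control, 31 of them at 4-fold or more. Pc_TC140225 was 1 of these. The set may therefore be mixed.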

How the results depend on the processing

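With 1 library per treatment no library could be left out and no other division of the libraries was possible, so these alternatives vary the processing only. The alternatives without the set missing from the 700 mM NaCl library, without the transcripts seen only in the control, and with thinned reads were chosen after seeing the data. Of 280 counts compared over 10 alternatives, 193 stayed within 1.5 times the reported value and 87 did not. These counts do not follow single transcripts. Part of the 193 could not move: leaving out the transcripts seen only in the control, for example, cannot touch higher calls against it. The limit to differences beyond counting error left every 2-fold call as it was. The tally thus overstates how stable the counts are. The majority direction of the calls turned in several settings, among them these: median-of-ratios scaling took the share of higher calls from 46.3% to 61.1% for 450 mM NaCl against control and from 48.1% to 58.8% for 700 mM, and a pseudocount of 1 took it from 52.1% to 36.5% for 700 mM against 450 mM. Counts depended on the pseudocount and the filter: the median called transcript reached RPKM 1.90 to 3.94 in the higher library, depending on the comparison and direction. Pairs below are higher, then lower. With a pseudocount of 0.1, calls were 3110 and 4552 for 450 mM NaCl against control, 5550 and 5868 for 700 mM, 4564 higher for submergence in salt, 5100 higher for 700 mM against 450 mM, 8609 higher for submergence in salt against 450 mM NaCl, and 6740 lower for submergence in salt against submergence in water. Shared calls were then 563 and 1751 for salt, 6193 and 5710 for submergence, 661 and 2294 for the 2 salt doses, and 2807 higher for the submerged treatments against control, with 2016 above and 2845 below additivity. With a pseudocount of 1, calls were 1111 and 1208 for 450 mM NaCl, 1600 and 2129 for 700 mM, 6059 higher for submergence in water, 1332 and 3180 for submergence in salt, 1220 higher for 700 mM against 450 mM, 3105 and 3980 for submergence in salt against 450 mM NaCl, and 2248 and 2232 for it against submergence in water. Shared calls were 70 and 172 for salt, 1936 and 2473 for submergence, 78 and 756 for the salt doses, and 778 and 2649 for the submerged treatments against control, with 201 above and 641 below additivity. Without a filter, calls were 3432 and 3616 for 450 mM NaCl, 5349 lower for 700 mM against 450 mM, and 402 higher at both salt doses. With a filter at RPKM 5, which tests fewer transcripts, calls were 421 and 306 for 450 mM NaCl, 864 and 845 for 700 mM, 3753 and 3564 for submergence in water, 894 and 1579 for submergence in salt, 520 and 540 for 700 mM against 450 mM, 1946 and 2295 for submergence in salt against 450 mM NaCl, and 1497 and 1267 for it against submergence in water. Shared calls were 74 and 220 for salt, 2009 and 1889 for submergence, 45 and 197 for the salt doses, and 542 and 1429 for the submerged treatments against control, with 212 above and 380 below additivity. Median-of-ratios scaling gave 276 transcripts higher in both salt contrasts and 440 higher at both salt doses. Its log2 factors relative to control were −0.16 at 450 mM and −0.10 at 700 mM NaCl. They were −0.03 in submergence in salt and 0.02 in submergence in water. Dividing by these factors raises all the salt ratios concerned, which adds higher calls. Why the factors differ between libraries was not tested. The limit to differences beyond counting error left 339 transcripts above additivity. Leaving out the set missing from the 700 mM library gave 1062 higher at 450 mM NaCl, 1252 lower at 700 mM against 450 mM, and 496 below additivity. Detected transcripts at RPKM of at least 1 were 65480, 61939, 64328, 66377 and 63095 (water control, 450 mM, 700 mM, submergence in water, submergence in salt), and the 10 most abundant transcripts held 2.74%, 2.85%, 3.28%, 3.45% and 2.61% of summed RPKM. Equal sums of RPKM, thinned reads and leaving out the transcripts seen only in the control moved none of the counts by more than 1.5 times. Sums over the transcripts of a gene were not run, because the transcript numbers name no locus. Depth limits low transcripts most: the median transcript had 22 to 32 reads per library.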

Other observations

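The tests of explanations in this part were all chosen after the results were seen, as was the choice of the patterns.

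The step from 450 mM to 700 mM NaCl and submergence in water lay along opposed directions. The log2 ratios of 700 mM to 450 mM NaCl ran against those of submergence in water to control (Pearson r −0.31, Spearman rho −0.31, 85583 transcripts), although these contrasts share no library. The log2 ratios of 700 mM NaCl to control likewise ran against those of submergence in salt to 450 mM NaCl (r −0.32), and along with those of salt under water (r 0.42). Transcripts called higher at 700 mM NaCl had a median log2 ratio to control of −0.48 in submergence in water, and those called lower there had a median of 0.40, or 0.25 without the set missing from the 700 mM library. In plants submerged in salt the medians of these groups were −0.13 and −0.14. At 450 mM NaCl the values pointed both ways. Transcripts higher at 450 mM had a median of 0.88 in submergence in water (0.39 without the set missing from the 700 mM library), and those lower at 450 mM had a median of −0.37 (−0.35 without the set). Both ratios in these medians use the same control library, which pulls them toward a like sign by an amount not measured here. Transcripts called higher under water had a median of −0.16 at 450 mM (−0.22 without the set) and those called lower 0.06, against that pull. Whether 450 mM NaCl shares the opposition is therefore left open.

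Transcript length as an explanation for this opposition is argued against by the values. Counting noise is independent between contrasts that share no library, so it could not give the opposition. In simulated libraries with no difference, r of 700 mM to 450 mM NaCl with submergence in water to control was at most 0.012 in size. The r of −0.36 at RPKM of at least 10 is therefore no separate evidence against counting noise. In 4 classes of transcript length the value nearest to 0 was −0.23, against a bias with length. Without the set missing from the 700 mM library r was −0.26, so that set alone does not account for it as a whole. Transcripts of a possible other organism with fewer reads can remain after its removal. Such an organism is therefore not excluded as a contributor. A difference in tissue make-up or harvest time between the libraries cannot be told apart from the treatments, since 0 marker transcripts could be named. A physiological opposition of the higher salt dose and submergence remains a hypothesis among these and was not tested.

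Calls against the water control were more often lower among the later transcript numbers than among the earlier ones, with the list divided at its middle. The share of calls that were lower was 38.4% against 64.4% (earlier against later) for 450 mM NaCl, 40.6% against 60.7% for 700 mM, 38.1% against 58.5% for submergence in water and 52.1% against 74.0% for submergence in salt. Length bias should remove the gap within 4 classes of transcript length. The smallest gap was 11.5 points for the submerged treatments and 24.96 for the shorter transcripts (2 of the 4 classes) at 450 and 700 mM NaCl. These values argue against length bias. In the classes of longer transcripts the gaps were −1.74 and −6.17 points at 450 mM and 10.9 and 0.76 at 700 mM, where length bias stays open. Assembly of the later transcripts from control reads may give such a gap, which should then be absent without the control. With the control the gaps were 20.1 to 26.0 points, and without it they were −2.30 points for 700 mM against 450 mM NaCl, 8.97 for submergence in salt against 450 mM NaCl and −5.50 for submergence in salt against submergence in water, which goes with this explanation. Within length classes these comparisons ran from −6.41 to 8.08, from −0.78 to 21.5 and from −17.0 to 11.98 points, so the explanation stays open, and no biological explanation was tested. Among numbers 60001 to 80000, most of them before the middle, the median RPKM was 0.23 in the control and 0.37 to 0.49 in the treatments. In every range from 80001 on, the control had the highest median of the 5 libraries. Part of the gap may thus lie in the earlier numbers, which assembly of the later ones would not cover.

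The 273 transcripts seen only in the control had a median length of 257 nt and 12072 control reads.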
